A study of Homo sapiens with 4 samples.

How the data were processed

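The samples were 4 cultures of the glioblastoma cell line LN-229, 2 without induction and 2 given doxycycline for 48 h to express WIF1. Per the labels, total RNA was extracted, amplified to biotin-labelled cRNA and hybridised to 1 array per culture, and the replicates are biological. The values deposited by the authors are log2 intensities per probe set, made with RMA in the R package affy per the submitters' processing notes, with no version given in the sources used here. RMA subtracts background, makes the distributions of probe intensities equal between arrays (quantile normalisation) and summarises the probes of a set on a log2 scale. A change shared by most genes would therefore not be seen, and differences near the floor are compressed. The values ran from 1.70 to 14.5 on the log2 scale, with like quartiles in each array. No scanner files were used here.

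Of 54675 rows, 62 control probe sets were kept out of the tests, which left 54613. Gene names came from the platform annotation given for these probe sets, which gives 41091 of them 1 gene symbol, 1801 several and 11721 none, and 41037 were matched by gene identifier to the RefSeq gene table of GRCh38.p14, where 0 symbols changed. Probe sets with several symbols were not named. Each of 19775 genes was represented by its probe set with the highest mean over the 4 arrays.

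Groups were taken from the sample titles. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment over the 54613 probe sets and a threshold of 0.05. The moderated test had 6.27 degrees of freedom, 4.27 of them from the prior. Standard errors are those of this model. 21 probe sets without any spread within groups were offset from 0 by the tool. The log2 changes were not shrunken, and array number limits their precision.

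The 33 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 756 listed genes 699 were measured, and the others are not used here. Listed symbols were looked up as current names, or as older names where they are not the current name of any gene. Lists were tested with camera on the representative probe sets (inter-gene correlation set to 0.01, 2-sided, adjusted over the 33 lists, at least 5 measured genes), again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. None of the 6 lists called by camera held with an estimated correlation, and 3 passed fry (integrated stress response, NF-kappaB and YAP/TAZ, each with adjusted p = 0.0445). The estimate was 0.33 for the mitosis list and under the preset 0.01 for the other called lists, at -0.046 to -0.019. With 4 arrays that setting leaves few degrees of freedom, and the smallest camera p of any list before adjustment was 0.0166. Apart from mitosis, the loss therefore does not show that correlation between genes made the calls. Where a list's shift is given in the section on processing choices, it is the list median minus the median of all genes.

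Named genes were WIF1, then MALAT1 and WNT5A from knowledge of the published study on these cells, then the 10 genes with the largest positive and the 10 with the largest negative log2 change among those with an adjusted p under 0.05, a mean at or above the median of all probe sets (6.16) and no overlap between groups. Where fewer met this, the list was filled up with the genes of smallest unadjusted p that met the conditions on mean and overlap, said not to pass, and this gave all 20 genes here. From each gene list up to 4 members of smallest p were added where the list was called or had a called member, and otherwise up to 2, with the same minimum mean. Members of lists that were not called could be left out. Other genes printed were chosen after their values were seen. They are EPOR, IL1A, PSPH, TRIB3, ASNS, ATF4, PHGDH, NFKBIA, IGFBP7, ANLN, CCNA2, AXIN2, LEF1, MYC, CCND1 and CDKN1A, the shared list members without values, and genes named only in the closing section.

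Alternatives were a replicate block, eBayes without the trend and with robust estimation, filters on dim probe sets (mean at or above the median, or at least 4), arrays centred on their medians, cyclic loess, probe sets averaged per gene or chosen before the fit, adjusted p thresholds of 0.01 and 0.1, and leaving out each array in turn. After leaving out an array, the lone array of its group is assumed to vary like the other group. One alternative, another probe set for MALAT1, was chosen after seeing the data.

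The test was tried on simulated data with the real probe set means, 200 changed probe sets and 10 simulations. Spreads were drawn from the prior that limma fitted to these data, so the simulated data follow the model of the test. It recovered 34.8% of changes of 0.5 log2 units, 91.3% of changes of 1 and 99.8% of changes of 2, and 3.96% of the 1566 calls were false. These shares depend on the number and size of the planted changes, because the adjustment is milder where many probe sets change. With fewer changed probe sets, less would be recovered. A list shifted by 0.15 was called by camera in 10 of 10 simulations, and 0 of 320 unshifted lists were called. The simulated genes were independent of each other, so this does not give the false call rate of camera for correlated genes.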

Results

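Gene expression was measured on 4 Affymetrix 3' expression arrays of LN-229, an established human glioblastoma cell line. In 2 arrays the cells had been given doxycycline for 48 h to switch on WIF1, a secreted protein that binds WNT ligands and keeps them from their receptors, and 2 arrays came from cells without induction. The labels call the replicates of each group biological. The values are log2 intensities of 54613 probe sets per array, with array medians of 6.16 and 6.19 in the controls and 6.15 and 6.15 after induction. Precision was limited by the 2 arrays per group, and all differences below are induced minus control with n = 2 in each group.

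The question of the comparison was what induced WIF1 does to the transcriptome of these cells. The induced arrays had higher signals for genes of the integrated stress response, led by CTH (cystathionine gamma-lyase, which makes cysteine) at 2.41-fold, and for NF-kappaB targets such as the cytokine IL6 at 2.01-fold. Target genes of YAP and TAZ, such as F3 (tissue factor), were higher as a group, and genes of cholesterol synthesis and of mitosis were slightly lower as groups. With an estimated correlation between genes 0 of the 6 called lists passed (adjusted p from 0.434 to 0.774), and the mitotic shift was also lost without the first control array (camera adjusted p = 0.660). With 4 arrays the estimated correlation leaves the test few degrees of freedom, so a list can be lost without correlated genes. For the mitosis list, however, the estimate was 0.33, against the preset 0.01. With the preset value, camera compares the genes of a list with other genes. Its p values then do not measure the spread between cultures. Target genes of the canonical WNT pathway were not called as a group. These shifts were seen over gene lists, and no single gene passed the test: limma called 0 of 54613 probe sets and 0 of 19775 genes at an adjusted p under 0.05. That count depended on the processing, with 2 genes called by robust eBayes, 4 after centring arrays on their medians and 9 each after cyclic loess, averaging of probe sets or 1 probe set per gene, all higher and always with SNAPC1 and CTH.

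WIF1 itself was read by 1 probe set near the floor of the array. Its log2 intensities were 2.98 and 2.90 in the controls and 2.93 and 3.03 in the induced arrays, a difference of 0.04 (SE 0.10, adjusted p = 0.911) that was smaller than the spread between replicates. The mean level of 2.96 lay at the 5.75 percentile of all probe sets. Whether this probe set lies within the expressed WIF1 sequence is not known here, so the labels of the induced arrays could not be checked through it.

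At an unadjusted p under 0.05 stood 5469 probe sets, 2593 higher and 2876 lower, where 2730.65 would be reached with no effect. Subtracting each array's median turned this split to 3477 higher and 1869 lower. The excess over 2730.65 was lost without the second control or the second induced array, and stayed without either other array. Such fits leave 1 array in a group and have less power. Among representative probe sets, 2217 genes had an unadjusted p under 0.05, 1281 higher and 936 lower, where 988.75 would be reached with no effect. That excess was also lost without the second control array and nearly lost without the second induced array. Both induced arrays lay on the same side of both controls in 41.4% of probe sets, against 33.3% by chance for 2 against 2. The smallest adjusted p values were 0.0794 for SNAPC1, a subunit of the complex that binds promoters of small nuclear RNA genes and activates them, and 0.0994 for CTH. The 4 genes that differed by at least 1 log2 unit, picked out by that size, were CTH at 1.27, IL1A at 1.23, EPOR at 1.10 and IL6 at 1.01.

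The 10 named genes higher in the induced arrays were taken by smallest p, since none passed the adjusted threshold. SNAPC1 was 0.63 higher (SE 0.036), with 10.93 and 10.91 in the controls and 11.53 and 11.57 after induction. CTH was 1.27 higher (SE 0.084), from 6.96 and 6.87 to 8.09 and 8.27. Its other probe set gave 0.58. The cytokine IL6 was 1.01 higher (SE 0.088, adjusted p = 0.160), and SCG2, the neuropeptide precursor secretogranin II, was 0.82 higher (SE 0.079, adjusted p = 0.167). The stress-responsive genes ATF3, GADD45A and GADD45B differed by 0.57, 0.48 and 0.56, each with an adjusted p of 0.167. The other probe sets gave less, 0.32 and 0.15 for ATF3 and 0.20 to 0.36 for GADD45B. F3 differed by 0.55 (SE 0.048), the small MAF factor MAFF by 0.40 (SE 0.032) and TIPARP, an ADP-ribosyltransferase, by 0.38 (SE 0.039).

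The 10 named genes lower in the induced arrays had adjusted p values from 0.227 to 0.433. IGFBP5, which binds insulin-like growth factors, was at 8.17 in both controls and at 7.48 and 7.24 after induction, a difference of -0.81 (SE 0.091). Its 6 probe sets all pointed down, from -0.81 to -0.07. The heparan sulfate proteoglycans SDC3 and SDC2 differed by -0.37 (SE 0.057) and -0.26 (SE 0.042). RAB17, a small GTPase, differed by -0.44, the sialyltransferase gene ST8SIA5 by -0.44, TMEM100 by -0.50 and NCALD, a neuronal calcium sensor, by -0.39. Lipoprotein lipase (LPL) stood at -0.30, podocalyxin (PODXL) at -0.31 and the phosphatase ACP6 at -0.26. The other probe sets of LPL and ACP6 gave -0.12 and -0.06. Those of SDC2 gave -0.19 and -0.11, and those of ST8SIA5 -0.28 and -0.27. The dim other probe sets of SDC3 and NCALD gave -0.02 and -0.13.

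**Figure D1:**
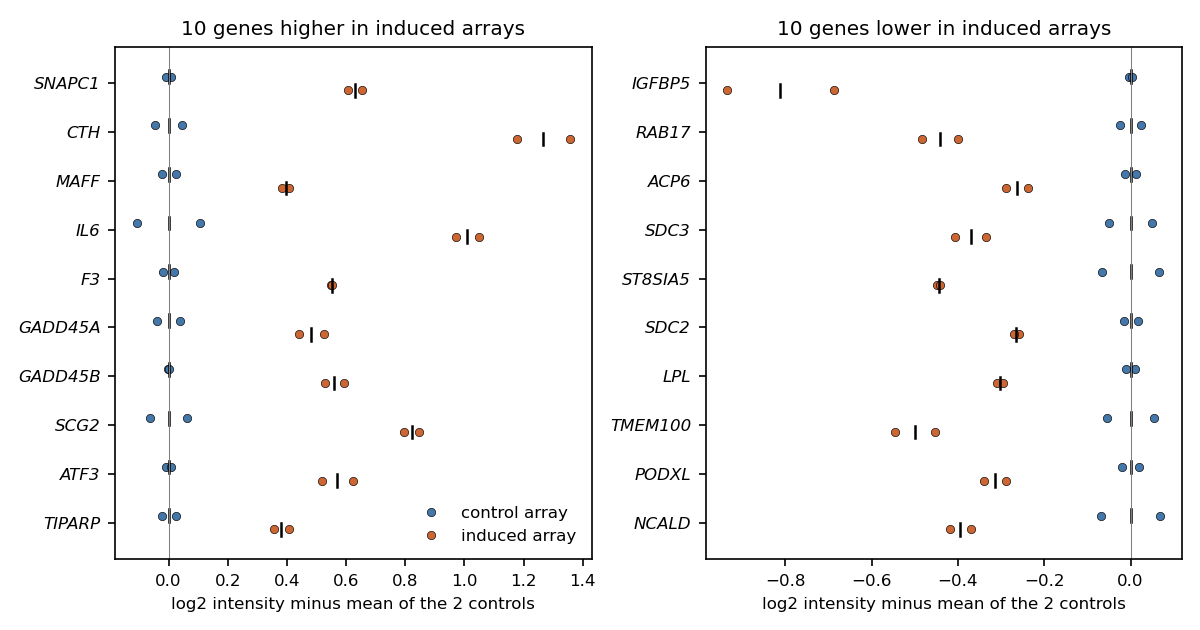
Log2 intensity of each array minus the mean of the 2 controls (x axis) for the 10 genes with the smallest p in each direction, with 1 point per array and a tick at each group mean. CTH and IL6 differed by 1.27 and 1.01 and IGFBP5 by -0.81, and none of the 20 genes had an adjusted p under 0.05.

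The integrated stress response and ATF4 target list rose as a group, with a median log2 change of 0.14 over its 31 measured genes (camera adjusted p = 6.0e-10, and adjusted p = 0.434 with an estimated correlation). Of these genes 26 were higher and 5 lower by sign, and 14 were higher and 1 lower at an unadjusted p under 0.05. None passed over all probe sets, and adjusted over the list alone 9 were higher and 1 lower. Besides CTH and ATF3, members with a small p included the serine synthesis enzyme PSPH at 0.53 (SE 0.11), the transcription factor DDIT3 (CHOP) at 0.48 (SE 0.052), the secreted glycoprotein STC2 at 0.46 (SE 0.047) and TRIB3 at 0.37 (SE 0.047). Asparagine synthetase (ASNS) was 0.33 higher, and ATF4 itself 0.10. PHGDH, the entry enzyme of serine synthesis, was the lower member at -0.17 (SE 0.044). In the second induced array the spiked-in dap control had a 3' minus 5' log2 difference of 2.81, against 2.30 to 2.40 in the other arrays. Without that array the median of the list was 0.12. For ACTB this 3' minus 5' difference was -0.036 and 0.021 in the controls and 0.033 and 0.11 after induction. For GAPDH it was -0.067 and -0.069 in the controls and -0.043 and -0.047 after induction. Leaving out 1 array does not address a bias in both.

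The NF-kappaB target list rose with a median of 0.16 over 21 genes (camera adjusted p = 3.59e-05, and adjusted p = 0.434 with an estimated correlation). At an unadjusted p under 0.05, 9 members were higher and 0 lower, and adjusted over the list alone 8 were higher. Its 4 members of smallest p were the cytokine IL6 at 1.01, the chemokines CXCL8 at 0.56 (SE 0.063) and CXCL1 at 0.29 (SE 0.050), and PTX3, a secreted pattern recognition protein, at 0.38 (SE 0.049). The inhibitor NFKBIA, a common feedback target of NF-kappaB, differed by -0.01 (SE 0.048). The list of the senescence-associated secretory phenotype, which shares IL6, CXCL8, CXCL1, CXCL2, CCL2, CCL20 and ICAM1 with it, rose with a median of 0.09 over 23 genes (camera adjusted p = 0.00954, and adjusted p = 0.491 with an estimated correlation). Adjusted over that list alone, 8 members were higher, with the dim IL1A at 1.23 (SE 0.099) and VEGFA at 0.42. Another 2 were lower, IGFBP5 and IGFBP7 at -0.81 and -0.16. The VEGFA value rested on 1 probe set, since its 3 others gave 0.02 to 0.13. Without the first induced array the camera adjusted p of the secretory list was 0.187, and over probe sets at or above the median it was 0.0528.

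The YAP/TAZ target list rose with a median of 0.08 over 19 genes (camera adjusted p = 7.66e-05, and adjusted p = 0.434 with an estimated correlation). At an unadjusted p under 0.05, 5 members were higher and 0 lower, and the same 5 passed adjusted over the list alone. They were GADD45B at 0.56, F3 at 0.55, the LIM protein AJUBA at 0.50 (SE 0.053), and the matricellular proteins CCN1 at 0.30 (SE 0.046) and CCN2 at 0.13 (SE 0.031). The other 14 members lay between -0.14 and 0.17.

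The cholesterol synthesis and SREBP2 target list fell, with a median of -0.07 over 19 genes and 16 of them lower by sign (camera adjusted p = 0.00336, and adjusted p = 0.491 with an estimated correlation). The isomerase IDI1 differed by -0.24 (SE 0.053), HMGCS1, which makes the HMG-CoA of this pathway, by -0.20 (SE 0.076), MVD by -0.18 and the sterol carrier STARD4 by -0.18. These were the 4 members lower at an unadjusted p under 0.05, and adjusted over the list alone 0 passed. The mitosis and G2/M list fell with a median of -0.06 over 30 genes (camera adjusted p = 0.00503, and adjusted p = 0.774 with a correlation estimated at 0.33). At an unadjusted p under 0.05, 6 members were lower and 2 higher, and adjusted over the list alone 0 passed. The kinetochore protein CENPF differed by -0.19 (SE 0.037), the spindle factor TPX2 by -0.15 (SE 0.040), CENPA by -0.15 and PRC1 by -0.13, while ANLN and CCNA2 were at 0.23 and 0.12. The 2 other probe sets of CENPF gave -0.20 and -0.01. This mitotic shift rested on the first control array, since without it the camera adjusted p was 0.660. The DNA replication list was not called (adjusted p = 0.486), with PCNA at 0.14 and RRM2 at -0.12.

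**Figure D2:**
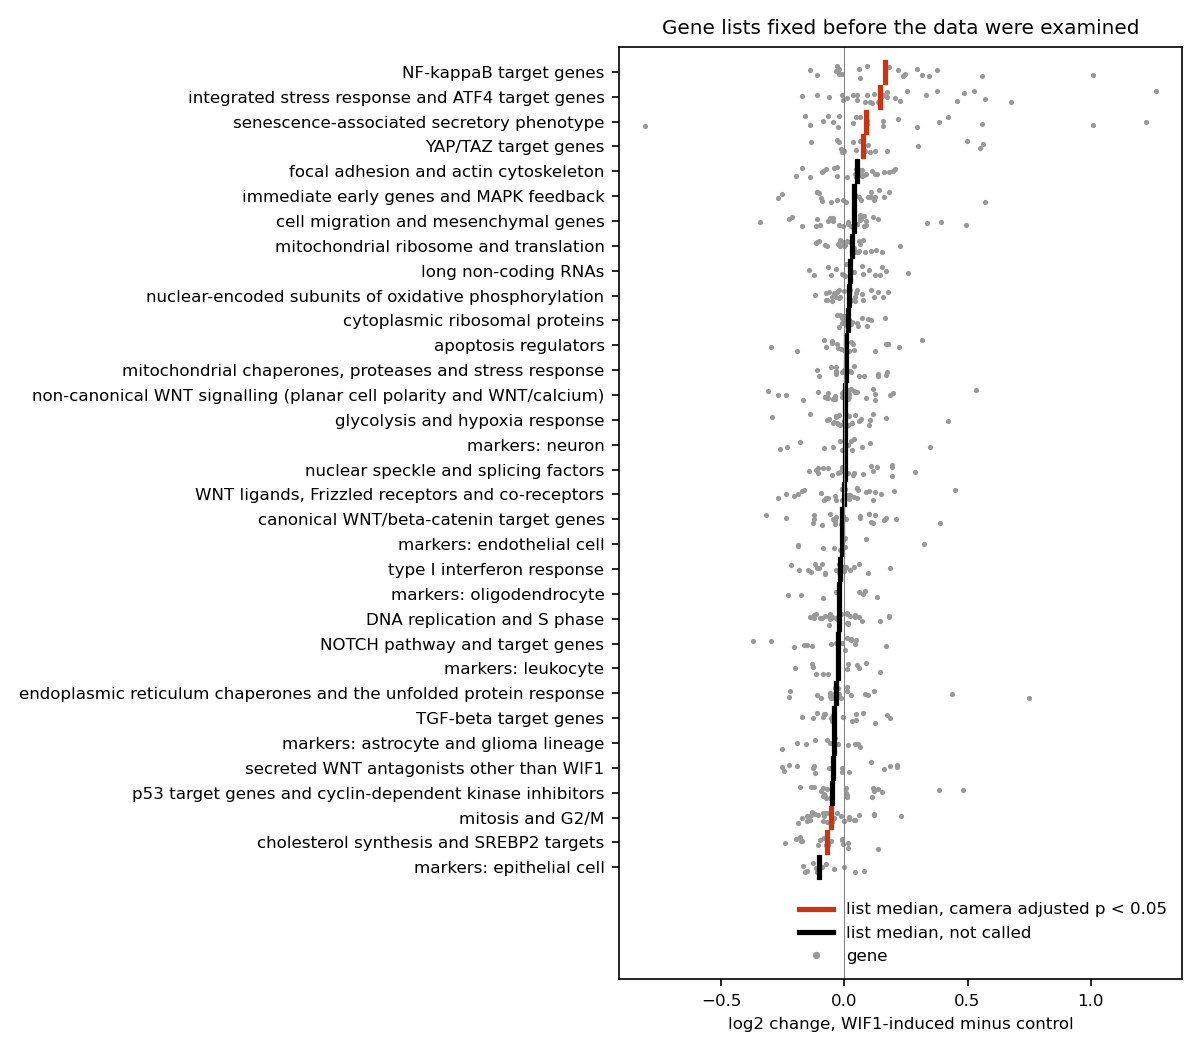
Log2 change, induced minus control (x axis), of each measured gene (grey points) in the 33 gene lists (y axis, ordered by median), with a vertical bar at each list median. Red bars mark the 6 lists with a camera adjusted p under 0.05, from a median of 0.16 for NF-kappaB targets to -0.07 for cholesterol synthesis.

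None of the 4 WNT lists was called. Canonical WNT/beta-catenin targets had a median of -0.01 over 26 genes (adjusted p = 0.745), where the mean and the test pointed up. AXIN2, the usual reporter of this pathway, differed by -0.06 (SE 0.078), LEF1 by -0.01 and MYC by 0.00, all within 1 SE. At an unadjusted p under 0.05, 5 members were higher, among them the cyclin CCND1 at 0.21 and the secreted antagonist DKK1 at 0.11, and 3 were lower, among them BAMBI at -0.13. WNT ligands, Frizzled receptors and co-receptors were not called (adjusted p = 0.700), with the co-receptor LRP6 at -0.21 (SE 0.056) and the receptor FZD7 at -0.19 (SE 0.054). Secreted WNT antagonists other than WIF1 were not called either (adjusted p = 0.715), and SFRP1 differed by -0.23 (SE 0.069). Non-canonical WNT genes had a median of 0.00 over 36 genes (adjusted p = 0.938), but adjusted over the list alone 1 was higher and 1 lower. The former was the phospholipase PLCB4 at 0.53 (SE 0.072) and the latter the calcium-responsive factor NFATC2 at -0.31 (SE 0.065), both in the WNT/calcium branch.

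WNT5A, a ligand of that branch, and the nuclear long non-coding RNA MALAT1 were named beforehand from knowledge of the published work on these cells. WNT5A was at 10.64 and 10.46 in the controls and at 10.67 and 10.68 after induction, a difference of 0.12 (SE 0.063, adjusted p = 0.546), and its other probe set gave 0.21. The brightest MALAT1 probe set differed by -0.05 (SE 0.10, adjusted p = 0.884), and by 0.12 without the second induced array. The 12 probe sets of MALAT1 disagreed, from -1.06 to 0.24. Of the 2 with the most negative differences, the brighter had log2 intensities of 10.54 and 11.21 in the controls and 10.03 and 9.61 after induction, a difference of -1.05 (SE 0.23, adjusted p = 0.472), and the dimmer gave -1.06 (SE 0.23, adjusted p = 0.472). The probe set with the most positive difference gave 0.24 (SE 0.083, adjusted p = 0.472).

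**Figure D3:**
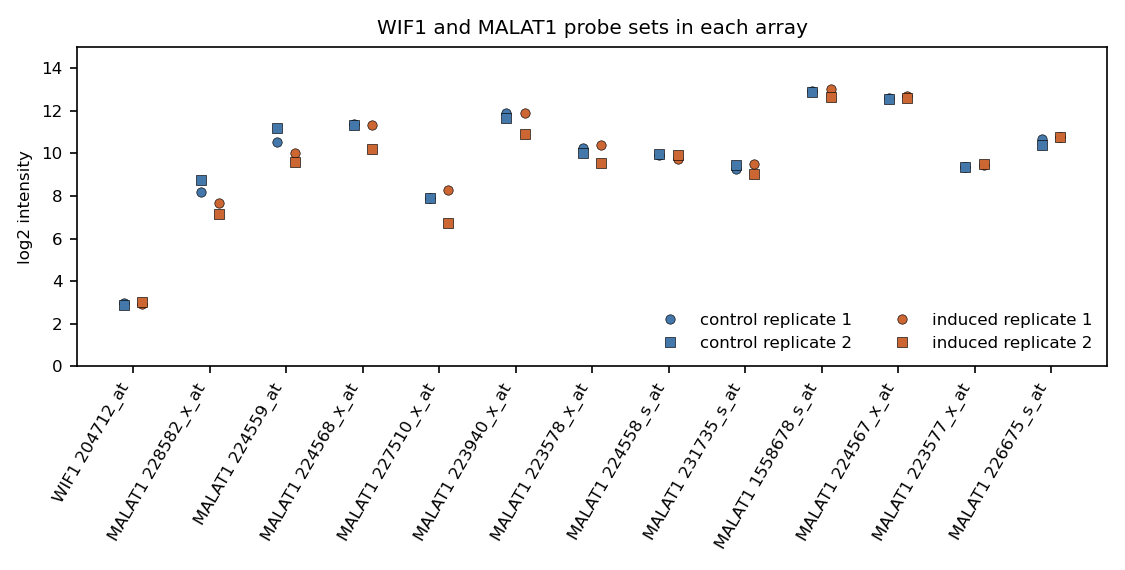
Log2 intensity (y axis) of the WIF1 probe set and the 12 MALAT1 probe sets (x axis, ordered by difference) in each of the 4 arrays. WIF1 stayed between 2.90 and 3.03 in all arrays, and the brighter of the 2 MALAT1 probe sets with the most negative differences was at 10.54 and 11.21 in the controls and at 10.03 and 9.61 in the induced arrays.

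Other lists fixed for these cells were not called. Target genes of p53 had an adjusted p of 0.938, with a median of -0.05, a mean of 0.02 and a test pointing down. Its member GADD45A, at 0.48, was higher adjusted over the list alone, RRM2B was at 0.38 (SE 0.12) and CDKN1A at -0.12 (SE 0.043), neither passing. Migration and mesenchymal genes (adjusted p = 0.745) held THBS1 at 0.39 and LOXL2 at -0.22, and focal adhesion genes (adjusted p = 0.138) held TPM1 at 0.16. Both THBS1 and TPM1 had probe sets that disagreed, from -0.27 to 0.39 over 7 and from -0.10 to 0.21 over 6. TGF-beta targets (0.745), immediate early genes (0.552), apoptosis regulators (0.801), the type I interferon response (0.265), glycolysis and hypoxia genes (0.727) and cytoplasmic ribosomal proteins (0.132) were also above the adjusted p threshold. Long non-coding RNAs (0.146), nuclear speckle and splicing factors (0.533), oxidative phosphorylation subunits (0.552), mitochondrial translation (0.210) and mitochondrial stress genes (0.715) did not pass either. Markers of the astrocyte and glioma lineage came closest (adjusted p = 0.0701), with FABP7, a radial glial fatty acid binding protein, at -0.19 (SE 0.034) and S100B at -0.12 (SE 0.038). Another bright probe set of FABP7 gave -0.06 and a dim one -0.29. Markers of neurons (adjusted p = 0.715, with a median above 0 and a test pointing down), oligodendrocytes (0.715), leukocytes (0.727), epithelial cells (0.129) and endothelial cells (0.745) were not called.

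The correlation over probe sets was 0.998 between the controls, 0.997 between the induced arrays and 0.996 to 0.998 across groups, where 3 of the 4 pairs lay below both replicate pairs and 1 above. With 2 arrays per group the 4 arrays allow only 3 splits, so the real one is 33.3% of them and no exact permutation test could reach 0.05, and none of the 4 arrays had doxycycline without WIF1.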

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

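Of the tests in this part, the one on tRNA synthetases was set before its result was seen, and those on chaperones, doxycycline, 3' bias, WIF1, MALAT1 and ribosomal RNA were chosen afterwards.

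Control probe sets stand outside the comparison, and 6 of 57 looked at were higher in both induced arrays than in both controls by more than the larger gap within a group, while 5 were lower by the same measure. All 6 read the 3' end of their transcript. They were the dap spike sets AFFX-DapX-3_at at 0.074 and AFFX-r2-Bs-dap-3_at at 0.15, the phe spike set AFFX-PheX-3_at at 0.13, the cre control AFFX-r2-P1-cre-3_at at 0.043, the ACTB 3' set at 0.042, and the 28S ribosomal RNA 3' set AFFX-M27830_3_at at 0.37. No biological explanation was tested for these.

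Genes of the integrated stress response and ATF4 list were higher in the induced arrays, with a median log2 change of 0.14. A general 3' bias of the second induced array alone is argued against by the median of 0.12 that remained without that array. A 3' bias shared by both induced arrays stays open, since leaving out that array does not address it. For ACTB and GAPDH the signal was shifted towards the 3' end in both induced arrays relative to both controls. For the dap spike this held in the second induced array only. Load on the endoplasmic reticulum that raises chaperones is argued against by the chaperone and unfolded protein response list. Its median of -0.036 had an upper 95% limit of 0.0087. Its camera adjusted p was 0.552, although SEC24D and XBP1 stood at 0.75 and 0.44. A wider ATF4 response may be present, since 11 cytosolic tRNA synthetases regulated by ATF4, held out of the list, had a median of 0.075 (limma camera adjusted p = 0.0173 over 3 held-out lists), with 9 of 11 higher by sign. The median of the 11 had an interval of -0.084 to 0.15, likewise over genes and without the spread between cultures. Their camera adjusted p was 0.330 with an estimated correlation, and 6 other synthetases had a median of -0.028. Doxycycline acting on the cells without WIF1 stays open, since no array had the drug alone and the mitochondrial stress list, at a median of 0.0083, does not decide it.

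WIF1, the gene induced by design, differed by 0.043 at its only probe set. A probe set outside the expressed sequence could give this, and so could a lack of induction in the arrays labelled induced. The 2 cannot be told apart, since the probe positions and the construct were not used here.

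The 2 MALAT1 probe sets with the most negative differences were lower in both induced arrays by about 1 log2 unit, at -1.05 and -1.06. A 3' bias of the second induced array is argued against as the whole cause, since without that array they stood at -0.84 (SE 0.29) and -0.81 (SE 0.26), while in 6 other MALAT1 probe sets that array alone lay below both controls. Without the second control array, the 2 differences were -0.72 and -0.77. Priming outside the poly(A) tail may still contribute, because both probe sets ranked the 4 arrays as the 18S ribosomal RNA signal did. That signal stood at 13.02 and 13.46 in the controls and 12.98 and 12.69 after induction, a difference of -0.41. A dimmer ribosomal RNA set, AFFX-M27830_3_at, ranked the arrays in the reverse order, with 5.98 and 5.91 in the controls. It stood at 6.18 and 6.45 after induction, a difference of 0.37. The ribosomal RNA signals therefore disagreed, and 4 arrays are too few to decide. A lower MALAT1 level with WIF1 stays open as well.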

How the results depend on the processing

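The alternatives were set before the data were examined, except for 1, the change to another MALAT1 probe set (-1.05), which was chosen after seeing the data. Signal over background limits dim genes such as WIF1, and the filters on dim probe sets gave WIF1 no value. Of the values of named genes other than WIF1 under alternatives, 1099 were as reported, 30 passed the threshold that the main test missed, and 3 turned sign. Robust eBayes called 2 probe sets and 2 genes (1 at least 2-fold, 1 list member), SNAPC1 and CTH. Median-centred arrays called 5 probe sets and 4 genes (3 at least 2-fold, 3 list members), cyclic loess 11 probe sets and 9 genes (3 and 7), averaged probe sets 9 genes (1 and 6) and 1 probe set per gene 9 genes (3 and 7), all higher and all including SNAPC1 and CTH. For the last pair fewer tests were adjusted for, and for the others the cause was not tested. An adjusted p under 0.1 called 2 probe sets and 2 genes, 1 of them 2-fold. Adjusted p values of SNAPC1 ran from 0.00986 to 0.901 over its alternatives, and leaving out any array left 0 calls. With the replicate block 0 probe sets were called (smallest adjusted p 0.587, 4424 at an unadjusted p under 0.05) and it changed no other call. Deviations of arrays with the same number correlated at 0.056 (0.107 over brighter probe sets), and 2 pairs do not show that the numbers pair the arrays. Leaving out 1 array gave -0.0070 to 0.092 for WIF1 and -0.23 to 0.12 for MALAT1, negative and positive without the second induced array. Averaging probe sets turned CALD1 to -0.051 and CLDN4 to 0.030.

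Of the 6 called lists, 0 passed with an estimated correlation (0.15 for the integrated stress response, 0.17 for NF-kappaB, 0.079 for YAP/TAZ, 0.092 for the secretory list, -0.069 for cholesterol and -0.053 for mitosis, shifts which this setting does not alter) and 3 passed fry, which lost the secretory (0.092), cholesterol (-0.069) and mitosis (-0.053) lists. The mitosis list was lost without the trend (-0.053, adjusted p = 0.0633), and ran from -0.091 to -0.022 as arrays were left out, lost without the first control. The secretory list was lost over brighter probe sets (0.13) and, in a range of 0.083 to 0.14, without the first induced array (0.095). Gained were DNA replication without the second control (range -0.035 to -0.0014), ribosomal proteins with centred arrays (0.016) and without the second control (range 0.016 to 0.022), though cyclic loess gave -0.028, and astrocyte markers with loess (-0.053), averaging (-0.076) and without the second control or second induced array (range -0.049 to -0.015). The NF-kappaB list stayed higher, with shifts from 0.11 to 0.22 over the alternatives that tested it. For the lists lost or gained the cause was not tested.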

Other observations

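Of the tests below, the one on aryl hydrocarbon receptor targets was set before its result was seen, and the one on splits of the arrays was chosen afterwards. The genes were picked after their values were seen.

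Both induced arrays had higher signals for SEC24D and XBP1, genes of the secretory pathway, with no matching difference in 2 of its chaperones. SEC24D, a cargo adaptor of the COPII coat, was 0.75 higher (SE 0.10, adjusted p = 0.338) at its brightest probe set, with a dim one at -0.25, and the transcription factor XBP1 0.44 higher (SE 0.073), while the chaperone HSP90B1 was at -0.22 (SE 0.062) and HSPA5 (BiP) at 0.01. The splicing kinase CLK1 was at 0.29 (SE 0.060), and the small nucleolar RNA host genes ZFAS1 and EPB41L4A-AS1 were at 0.17 and 0.26, both passing when adjusted over the list alone, although the other probe set of EPB41L4A-AS1 gave -0.02. Genes of the NOTCH pathway went both ways, with DTX1 at -0.37, NOTCH3 at -0.30 and the ligand JAG1 at 0.17, and the list was not called (adjusted p = 0.210). The pro-apoptotic gene BCL2L11 (BIM) was at -0.30 (SE 0.066) at its brightest probe set, and its 7 probe sets disagreed, from -0.30 to 0.24.

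PRNP, the prion protein gene, had 2 probe sets that moved apart, the brighter at 0.31 (SE 0.039) and the dimmer at -0.29 (SE 0.066), each with both induced arrays on one side of both controls.

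A candidate hypothesis was a response of the aryl hydrocarbon receptor, since its target CYP1A1 was at 0.61 (SE 0.085), AHR itself at 0.44 (SE 0.059) and TIPARP at 0.38, none of them passing. The 8 other targets tested, among them CYP1A2 at 0.26, the highest, CYP1B1 at -0.13, AHRR at 0.05 and NQO1 at -0.10, had a median of -0.093 with an upper 95% limit of 0.26 (limma camera adjusted p = 0.217), below the smaller of the 2 changes. A rise shared by these 8 targets was not seen, but CYP1B1, ALDH3A1 and CYP2S1 were dim (means 5.69, 5.79 and 5.42), where differences are compressed. The limit comes from a sign test over the genes, equals the highest of them and holds no spread between cultures. What raised CYP1A1 and TIPARP stays open.

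Of the 3 splits of the 4 arrays into 2 and 2, 1 gave at least as many probe sets at an unadjusted p under 0.05 as the real one, which is the real one itself with 5469. The highest of the others gave 1892, and each of the others called 1 gene list, against 6. In those splits any difference between the real groups counts as spread within groups and lowers the counts. They therefore do not show what no effect would give. The splits are too few for a share under 0.05. Without the second control or the second induced array, the real comparison fell under the 2730.65 reached with no effect, in fits with less power.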
